A study of Mus musculus with 10 samples.

How the data were processed

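Bulk RNA sequencing was performed on cells of the mouse dorsal brain that had been targeted at embryonic day 12 by in utero electroporation with StarTrack, a set of reporter plasmids used to follow the progeny of electroporated progenitors. Cells were dissociated at embryonic day 14 and sorted by flow cytometry as NG2+ or GFAP+, and the labels give 5 libraries for each population, all in batch 1. Per the labels' protocols, RNA was extracted with a micro-scale kit, amplified with the SMARTer chemistry, enriched for poly(A) transcripts and sequenced as paired ends on a NovaSeq instrument. Amplification of small RNA inputs without molecular identifiers can turn 1 molecule into many reads, so the counts of lowly expressed genes carry more error than their depth alone would give.

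The deposited read counts per gene were whole numbers in 1 column for each library, and they had not been normalised. The submitters' processing notes name HISAT2 as aligner, featureCounts 1.5.0-p3 as counter and GRCm38.p6 as genome build. The strand setting, the treatment of reads with several alignments and the annotation release are not given in the sources used here, so the genes named in the report that overlap another gene are given as uncertain. The deposited FPKM values were equal to the count divided by gene length and by 1 constant for each library, and that constant lay between 0.929 and 1.045 times the library's count total. The same table held the authors' comparison of the groups, made with a tool that the sources used here do not name. Per the file headers, it gives a mean signal for each group, which lay near the mean scaled count, and a log2 fold change with a p-value and an adjusted p-value. In the authors' deposited table, 94 genes without a p-value carried an adjusted p of 1. Gene starts, ends and lengths were used as deposited, with coordinates counted from 1 on GRCm38. Of the 53801 gene identifiers, 53620 were also found in the GENCODE M21 annotation of the same genome, from which GC content was taken. Gene overlaps were taken from the deposited coordinates. GC content and length were available for 16168 of the 16187 tested genes and for all 614 distinct tested members of the gene lists.

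The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM normalisation, edgeR's default expression filter by group and Benjamini-Hochberg adjustment over the genes that passed it. Log2 fold changes are NG2 minus GFAP throughout, with edgeR's estimate and its standard error. A threshold of 0.05 on the adjusted p was used. Expression levels are CPM, read counts scaled to a common library total with the TMM factors, and are given as mean ± SD over 5 libraries. Cspg4, which encodes NG2, and Gfap were compared by an exact permutation test of mean log2 CPM over all 252 assignments of the libraries, with both signs of the difference counted. The separation of the groups was measured as the mean distance between groups minus the mean distance within groups, with 1 minus the Pearson correlation of log2 CPM as the distance, and was tested over all 126 splits into 5 and 5.

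A set of 37 gene lists with 700 distinct symbols was fixed for cell types, developmental pathways, metabolism and RNA quality, and 696 of the symbols were found in the table. All lists had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside camera stand the p with a correlation estimated for each list, the rotation test fry, and an exact permutation test of a library's list score, which is the mean over members of the log2 difference from the gene's mean over the 10 libraries. Counts of list members past the threshold are given over all genes tested and also adjusted over the list alone.

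The tests, samples, gene lists, main alternatives and the rule for named genes were fixed before the data were examined. By that rule, Cspg4 and Gfap were always named. In each direction the rule took the 10 genes with the largest absolute fold change among protein-coding genes past the threshold that had a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes. From each list it took up to 4 members past the threshold or, where there were none, up to 2 with the highest mean CPM. Genes named outside this rule, apart from sex-linked genes, are described as chosen after their values were seen. These include every member named only because it passed when adjusted over the list alone. Values of some list members are not reported here.

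The alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no expression filter or a stricter one of 5 CPM in 5 libraries, the Wald test of DESeq2 1.42.0, voom with sample weights, limma-trend on the deposited FPKM with pseudocounts of 1 and 0.1, and protein-coding genes alone. The removal of mitochondrial, hemoglobin and ribosomal protein genes, a replicate block, covariates for library size and for genes detected, 1 surrogate variable (sva 3.50.0), a fold threshold and each library left out in turn were tried as well. After the data had been seen, a correction for GC content and length, DESeq2 without NG2 replicate 5, robust dispersions and the permutation of list scores were added.

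The main test was tested on simulated data for this comparison, drawn for 16187 genes from the means, dispersions and library sizes of these libraries, in 5 runs with 200 changed genes each. It called 37.6% of genes changed by 1.5-fold, 63.3% of those changed by 2-fold and 84.8% of those changed by 4-fold, and 4.63% of the genes called had not been changed. A list raised on purpose was called by camera in 5 of 5 runs, and 0 of 100 unchanged lists were called. These lists were simulated without correlation between genes, so this share does not measure camera's error for correlated lists. The simulation also held no library set apart like NG2 replicate 5 and no shift shared by many genes. The shares of genes called may therefore differ in the real data. Intervals on ratios of reads are 95% and cover counting error only. The labels do not say whether libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Counts of the 20 pairs of libraries within a group were compared over genes by chi-square, which averaged 6.18 to 50.7 for each gene. No pair agreed within counting noise, as 1 library deposited in duplicate would. Repeated preparations of 1 sample would also differ by more than this noise, so the test does not show that the libraries came from separate samples, which rests on the labels. GFAP replicate 5 differed from the others of its group in sex-linked transcripts, given below, so it was not a repeated preparation of their cells.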

Results

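Libraries were available from NG2+ and GFAP+ cells of the dorsal mouse brain, 5 from each population, after StarTrack targeting at embryonic day 12 and sorting at embryonic day 14. NG2 is a chondroitin sulfate proteoglycan encoded by Cspg4, and GFAP is an intermediate filament protein of astroglia. The labels call both populations neural stem cells, and the comparison between them asks whether cells sorted as NG2+ and as GFAP+ differ in the genes they express. Neurod6, a gene of differentiating neurons, stood at means of 1968 CPM in the NG2 and 1646 CPM in the GFAP libraries. The libraries thus did not hold progenitors alone. Library totals ranged from 12945436 to 17569730 counts, and reached 16189859 in the GFAP group and started at 14256176 in the NG2 group. The table held 53801 genes. The number of genes with at least 1 read was 23660 ± 380 in the GFAP libraries and 22644 ± 2162 in the NG2 libraries (mean ± SD, n = 5 each). NG2 replicate 5 had reads for 18903 genes although its total was the highest of the 10. Its log2 CPM correlated at r = 0.919 to 0.929 with the other 9 libraries, while the 36 pairs of other libraries reached 0.968 to 0.986 (across genes, which are not independent replicates). The share of counts from mitochondrially encoded genes was 0.589% ± 0.0448 in the GFAP group and 0.656% ± 0.0861 in the NG2 group (SD, n = 5). Hemoglobin genes made up 0.0247% to 0.0464% of counts.

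Cspg4 was 6.24-fold higher in the NG2 libraries, at 6.75 ± 1.47 CPM against 1.07 ± 0.356 CPM in the GFAP libraries (SD, n = 5 each). All 5 NG2 libraries lay above all 5 GFAP libraries. Odf3l1, the neighbouring gene, was found in the NG2 libraries at 8.77 ± 2.19 CPM and with 1 read in 1 GFAP library. Gfap was near the limit of detection in both groups and did not differ detectably. Cspg4 (ENSMUSG00000032911, chromosome 9, 56865033 to 56899870 on the plus strand, GRCm38) had a log2 fold change of 2.64 (SE 0.30, edgeR, Benjamini-Hochberg adjusted p = 0.00256). The exact permutation p of its mean log2 CPM was 0.00794, the smallest that 252 assignments can give. Odf3l1 (ENSMUSG00000045620, chromosome 9, 56848659 to 56864679, minus strand) was chosen after its values were seen. It lies head to head with Cspg4, with 353 bp between the 2 genes, and had 666 reads in the NG2 group against 1 read in GFAP replicate 2. The ratio of its depth-scaled reads was 642, with a 95% interval of 115 to 25400 (edgeR, Benjamini-Hochberg adjusted p = 1.03e-06). The 16 other tested genes within 500 kb had a median log2 fold change of -0.036, and 0 passed by edgeR. Transcripts of the electroporated NG2 reporter may contribute to the reads of both genes, as given under the other observations. The rise of Cspg4 therefore does not by itself show a difference in the cells' own Cspg4. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912, minus strand) had 6 reads in the NG2 group and 10 in the GFAP group, in 6 of the 10 libraries, or 0.0821 ± 0.148 and 0.128 ± 0.170 CPM. It did not reach the expression filter of edgeR. The exact permutation test gave p = 0.492 for a log2 CPM difference of -0.30, which turned to 0.02 (p = 0.968) without GFAP replicate 1. Gfap overlaps Gm26668 on the opposite strand, so the origin of these few reads is uncertain. At this depth, a difference in Gfap was not detectable in either direction.

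**Figure D1:**
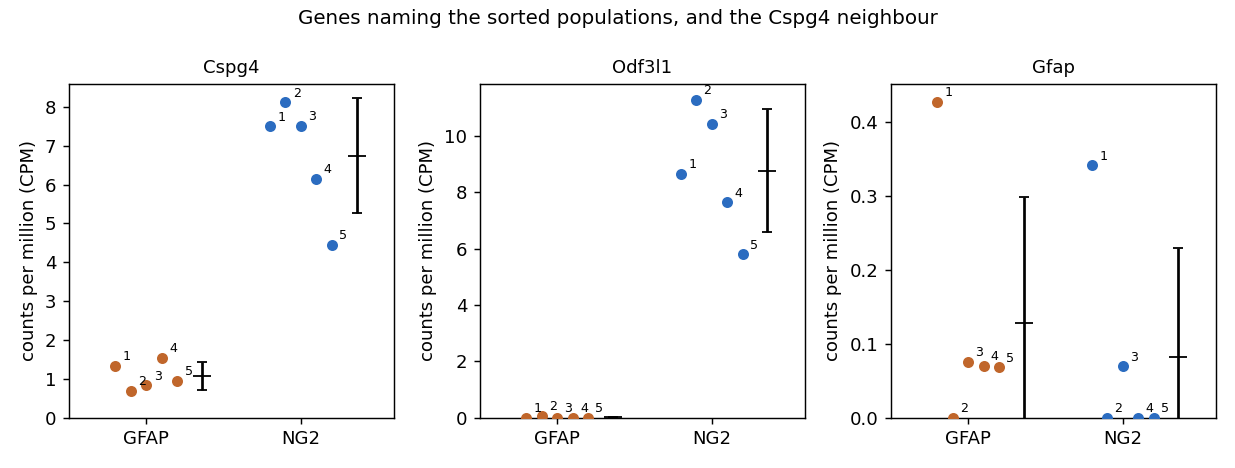
Expression of Cspg4, Odf3l1 and Gfap in CPM for each library, grouped as GFAP and NG2, with numbers giving the replicate and bars giving mean ± SD (n = 5), clipped at 0 for Gfap. The 5 NG2 libraries lie above the 5 GFAP libraries for Cspg4 and Odf3l1, and the Gfap panel spans values from 0 to 0.427 CPM.

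A small number of genes beside Cspg4 and Odf3l1 differed between the groups. Tfap2d, a transcription factor of the AP-2 family, was 2.38-fold higher in the NG2 libraries at 23.6 ± 5.75 against 9.89 ± 1.42 CPM, and Mc4r, the melanocortin 4 receptor, was 1.99-fold higher at 32.5 ± 2.33 against 16.3 ± 1.72 CPM (SD, n = 5). The LIM homeobox factor Lhx9 fell by 1.79 on the log2 scale in the NG2 libraries, from 8.18 ± 2.79 to 2.36 ± 0.915 CPM, and Zic5, a zinc finger transcription factor, fell by 1.25, from 10.2 ± 2.25 to 4.28 ± 0.448 CPM. Of 16187 genes tested, 12 were higher and 12 lower in NG2 by edgeR at an adjusted p of 0.05, and 2069 had an unadjusted p under 0.05. All 24 are protein-coding and had no overlap between the groups, which was also true of 531 of all tested genes (3.28%), where chance gives 0.794%.

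Among the higher genes, Tfap2d (ENSMUSG00000042596, chromosome 1, 19103022 to 19166346) had a log2 fold change of 1.25 (SE 0.18) and Mc4r (ENSMUSG00000047259, chromosome 18, 66857715 to 66860472) of 0.99 (SE 0.12), with edgeR Benjamini-Hochberg adjusted p = 0.0162 and 0.00337. The LIM cofactor Ldb2 rose by 0.84 (SE 0.15). Fam19a5, which encodes a small secreted protein, rose by 0.78 (SE 0.14), the synaptotagmin Syt16 by 0.76 (SE 0.14), and Syngr3, a synaptic vesicle protein, by 0.58 (SE 0.10). Cd200, a membrane ligand of a receptor on myeloid cells, rose by 0.65 (SE 0.11), the Polo-like kinase Plk2 by 0.62 (SE 0.11), the septin Sept5 by 0.60 (SE 0.11) and Kctd13, an adaptor of a ubiquitin ligase, by 0.58 (SE 0.10). The edgeR Benjamini-Hochberg adjusted p of these 8 genes lay between 0.0379 and 0.0444.

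Among the lower genes, Crb2, a member of the Crumbs complex, fell by 0.92 on the log2 scale (SE 0.16), Pard3, a scaffold of the apical polarity complex, by 0.61 (SE 0.11) and Mpdz, a scaffold with several PDZ domains, by 0.67 (SE 0.12). Fzd9, a Frizzled receptor for Wnt ligands, fell by 1.21 (SE 0.19), and Cdon, a co-receptor for Hedgehog ligands, fell by 0.71 (SE 0.11). Nfatc4, a calcium-regulated transcription factor (ENSMUSG00000023411, chromosome 14, 55823144 to 55833943), fell by 0.99 (SE 0.14), with an edgeR Benjamini-Hochberg adjusted p of 0.0162. Spata13 fell by 0.87 (SE 0.14) and the carbonic anhydrase Car14 by 0.86 (SE 0.15). Lhx9 (ENSMUSG00000019230, chromosome 1, 138825186 to 138848577, SE 0.32) and Zic5 (ENSMUSG00000041703, chromosome 14, 122456795 to 122465677, SE 0.21) had edgeR Benjamini-Hochberg adjusted p of 0.0429 and 0.0379. Over the alternatives, the log2 fold change of Zic5 ranged from -1.38 to -0.70 and that of Crb2 from -0.96 to -0.52. The last 2 of the 24 genes, Dct and Ndrg2, fell outside the naming rule and were chosen after their values were seen. Dct, an enzyme of melanin synthesis, fell by 2.10 (SE 0.35) to 1.86 ± 0.704 CPM, and Ndrg2 fell by 0.50 (SE 0.08) to 98.6 ± 4.42 CPM, both with edgeR Benjamini-Hochberg adjusted p = 0.0379. Tfap2d, Ldb2, Sept5, Kctd13, Crb2, Car14 and Cdon overlap another annotated gene, so part of their reads is of uncertain origin.

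**Figure D2:**
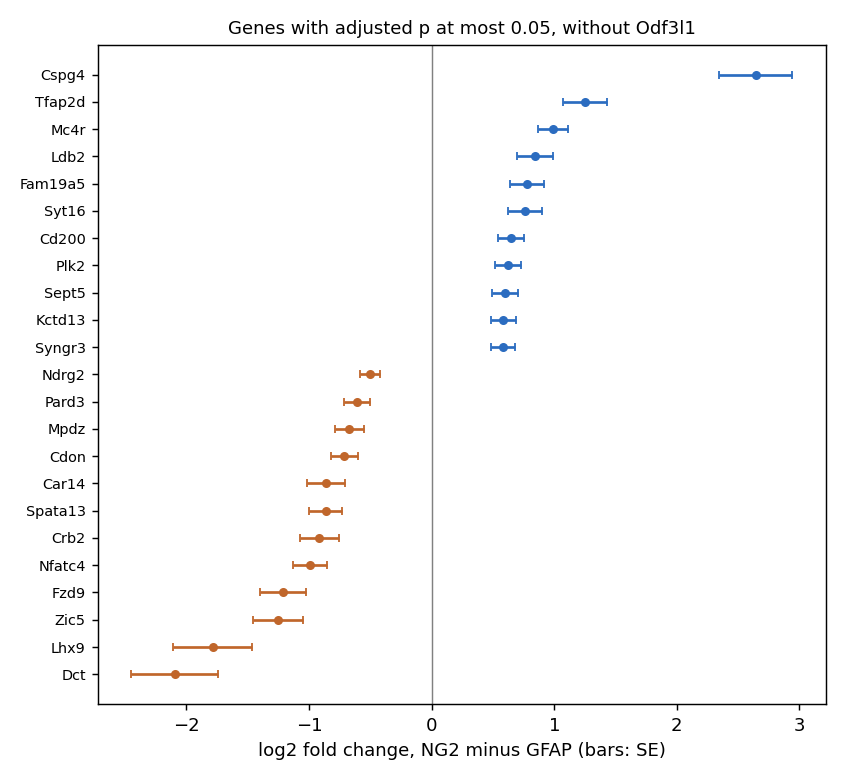
Log2 fold change (NG2 minus GFAP, horizontal axis) of the genes with an adjusted p of at most 0.05 by edgeR, with 1 point for each gene and bars giving the standard error. Odf3l1 is left out of the plot because it had 1 read in the GFAP group. Cspg4 lies farthest to the right at 2.64 and Dct farthest to the left at -2.10.

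The number of genes past the threshold changed when any 1 library was left out. By edgeR it was 3 higher and 0 lower without GFAP 1, GFAP 2, GFAP 3 or NG2 2, 4 and 1 without GFAP 4 or NG2 3, 4 and 2 without GFAP 5, 6 and 6 without NG2 4, 13 and 9 without NG2 1, and 70 and 47 without NG2 5, where all 24 remained. Cspg4, Mc4r and Odf3l1 stayed past the threshold in all 10 of these fits, and each of the other 21 genes lost it in 4 to 9 of them while keeping its direction. Each of these fits also had fewer libraries, so a lower count does not mark the library left out as its source. DESeq2 called 210 higher and 133 lower, and the authors' deposited table lists 203 higher and 129 lower, among them all 24. The deposited folds equal those of DESeq2 within 4.61e-05 and 331 of the 332 genes are shared with it, so these 2 sets of counts are not independent. With a correction for GC content and gene length, 20 genes were higher and 9 lower, so the share of higher genes was 69.0% against 50% without it, and with scaling by library size alone it was 40% (8 higher, 12 lower).

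Markers of radial glia, the neural stem cells that line the ventricle, and of the intermediate progenitors derived from them were lower in the NG2 libraries by camera. The calls held with its preset correlation and not with an estimated one. Of 27 tested radial glia genes, 25 had a negative and 2 a positive fold change, with a median of -0.36 on the log2 scale (-0.22 without GFAP replicate 2, -0.18 by voom with sample weights). Of 18 intermediate progenitor genes, 16 were negative and 2 positive, with a median of -0.30. Both lists were lower by camera, radial glia with a Benjamini-Hochberg adjusted p of 4.24e-07 and intermediate progenitors with 4.33e-05. With an estimated correlation between genes, camera's Benjamini-Hochberg adjusted p was 0.457 and 0.198, so neither call held. The estimated correlation was 0.56 for radial glia and 0.05 for intermediate progenitors. By the rotation test fry the Benjamini-Hochberg adjusted p was 0.126 for radial glia and 0.0114 for intermediate progenitors. Over all genes tested, 1 radial glia gene fell by edgeR, Pard3, against 0 with the GC and length correction and 7 by DESeq2. Adjusted over the list alone 10 fell and 0 rose. These include the transcription factors Lhx2 (log2 fold change -0.34, SE 0.08) and Sox3 (-0.73, SE 0.17), both chosen after their values were seen, and Id4 (-0.70, SE 0.16). Of the intermediate progenitor genes 0 passed over all genes tested, and adjusted over the list alone 7 were lower. These include Eomes, the T-box factor of intermediate progenitors, at 188 ± 22.3 CPM in NG2 and 249 ± 8.66 CPM in GFAP libraries, and the antiproliferative gene Btg2 at 208 ± 9.72 and 284 ± 28.9 CPM, both chosen after their values were seen. The members with the highest expression did not pass in either way. Sstr2, a somatostatin receptor, had a log2 fold change of 0.13 (SE 0.10) and the proneural factor Neurog2 of -0.21 (SE 0.10).

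Scores of the libraries differed in how the 2 lists separated the groups. The intermediate progenitor score was 0.14 ± 0.05 in the GFAP and -0.14 ± 0.08 in the NG2 libraries (SD, n = 5), with no overlap and an exact permutation p of 0.00794 (0.0587 after Benjamini-Hochberg adjustment over the lists). The radial glia score was 0.18 ± 0.20 against -0.18 ± 0.32 and overlapped (exact permutation p = 0.0556). GFAP replicate 2 scored 0.53 on the radial glia list and NG2 replicates 2 and 3 scored -0.60 and -0.45, while NG2 replicates 1, 4 and 5 scored 0.05, -0.02 and 0.11, within or close to the range of 0.04 to 0.13 of the other 4 GFAP libraries. Markers of meningeal fibroblasts, given with the other cell types, were also lower in NG2 (median -0.62). The same GFAP library stood apart in the G1/S list, at 0.76 against -0.12 to -0.04 in the others of its group.

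**Figure D3:**
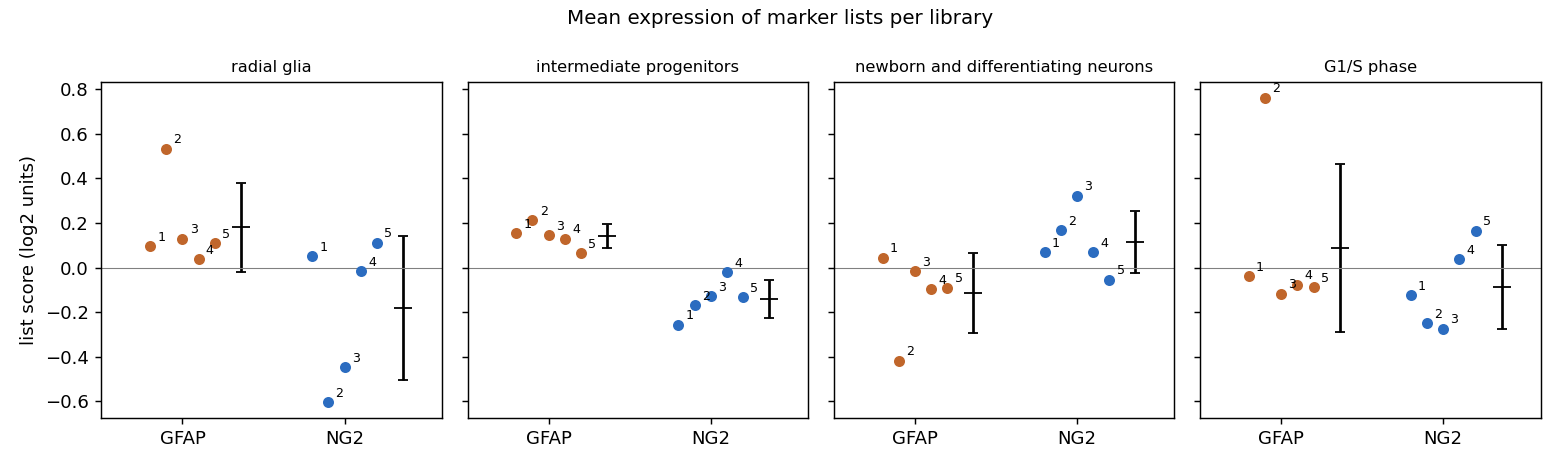
Score of 4 gene lists in each library (vertical axis, mean log2 difference of the members from their mean over all 10 libraries), with numbers giving the replicate and bars giving mean ± SD (n = 5). Intermediate progenitor scores do not overlap between the groups, and GFAP replicate 2 lies apart from its group in the radial glia and G1/S panels.

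Genes of newborn and differentiating neurons were higher in the NG2 libraries by camera with its preset correlation, but not with an estimated one. Of 26 tested, 20 had a positive and 6 a negative fold change (median 0.29 on the log2 scale, 0.16 by voom with sample weights), and the list was higher by camera (Benjamini-Hochberg adjusted p = 3.81e-05). With an estimated correlation, camera's Benjamini-Hochberg adjusted p was 0.457. No member passed over all genes tested by edgeR, with or without the GC and length correction. By DESeq2 7 were higher and 0 lower, and 2 were higher by edgeR without NG2 replicate 5. Adjusted over the list alone 9 were higher and 1 was lower. Among those 9, chosen after their values were seen, were the microtubule regulators Stmn2 (log2 fold change 0.62, SE 0.14) and Stmn3 (0.50, SE 0.13), the reticulon Rtn1 (0.56, SE 0.13) and the neurofilament gene Nefm (0.72, SE 0.17), which overlaps Nefl on the opposite strand. The neuronal factor Neurod6 stood at 1968 ± 428 CPM in the NG2 and 1646 ± 212 CPM in the GFAP libraries, and Tubb3, the neuronal beta tubulin, at 1639.5 ± 183 and 1289 ± 95.9 CPM. Their log2 fold changes of 0.26 (SE 0.14) and 0.35 (SE 0.10) did not pass over all genes tested by edgeR. The list score was 0.12 ± 0.14 in NG2 and -0.12 ± 0.18 in GFAP libraries (exact permutation p = 0.0397, 0.163 after Benjamini-Hochberg adjustment). GFAP replicate 2 scored -0.42, against -0.10 to 0.04 in the others of its group, and camera called the list in all 10 fits with 1 library left out (Benjamini-Hochberg adjusted p up to 0.00384). The microglia list (median 0.84) and the mitochondrially encoded transcripts (median 0.18) moved in the same direction.

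Synapse and ion channel genes were also higher in the NG2 libraries by camera (21 of 27 positive, median 0.20, Benjamini-Hochberg adjusted p = 0.000293). With an estimated correlation, camera's Benjamini-Hochberg adjusted p was 0.457. GFAP replicate 2 scored -0.51, against -0.06 to 0.11 in the others of its group, and the scores of the groups overlapped (exact permutation p = 0.222, 0.411 after Benjamini-Hochberg adjustment). Without that library the median was 0.13. Adjusted over the list alone 4 members were higher, against 0 over all genes tested. They include the synaptotagmin Syt4 (log2 fold change 0.63, SE 0.13) and the synapsin Syn1 (0.52, SE 0.13), both chosen after their values were seen. The glutamate receptor subunit Gria2 (0.17, SE 0.17) and the vesicle protein Vamp2 (0.27, SE 0.10) did not pass. Genes of deep-layer projection neurons were higher by camera (11 of 13 positive, median 0.19, Benjamini-Hochberg adjusted p = 0.0358). Camera's Benjamini-Hochberg adjusted p was 0.457 with an estimated correlation, and its preset value rose to as much as 0.175 when GFAP 2, NG2 1, NG2 4 or NG2 5 was left out. GFAP replicate 2 scored -0.47 on that list, against -0.12 to 0.19 in the others of its group (exact permutation p = 0.151 for the group scores). The median of the list was 0.33 without GFAP replicate 1 and 0.30 without NG2 replicate 3. Ldb2 was the 1 member that rose over all genes tested, and adjusted over the list alone the ligand Wnt7b, chosen after its values were seen, was higher too (0.57, SE 0.16). Upper-layer projection neuron genes had 8 of 14 positive and were not called (median 0.03, camera Benjamini-Hochberg adjusted p = 0.0959).

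Genes of Cajal-Retzius cells and subplate, the earliest cortical neurons, were lower in the NG2 libraries by camera (10 of 13 negative, median -0.42, Benjamini-Hochberg adjusted p = 0.00166), and with an estimated correlation camera's Benjamini-Hochberg adjusted p was 0.297. Scores of the groups did not overlap (exact permutation p = 0.00794, 0.0587 after Benjamini-Hochberg adjustment). Adjusted over the list alone 5 members were lower, against 0 over all genes tested. The lysophosphatidic acid receptor Lpar1 stood at 50.6 ± 7.07 CPM in NG2 and 69.4 ± 16.7 CPM in GFAP libraries, and the subplate factor Nr4a2 at 21.1 ± 3.70 and 30.2 ± 2.81 CPM. The Cajal-Retzius factors Trp73 (1.15 ± 0.389 against 2.86 ± 1.46 CPM) and Lhx5 (0.300 ± 0.263 against 1.28 ± 0.677 CPM), chosen after their values were seen, were lowly expressed. The median was -0.22 without NG2 replicate 2. Meningeal fibroblast genes (median -0.62) and genes of cortical hem and choroid plexus (median -0.53, not called) moved in the same direction, and GFAP replicate 1 had the highest score of the 10 libraries in all 3 lists, at 0.66, 0.96 and 1.84.

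Transcription factors and ligands of the caudal and medial cortex were lower in the NG2 libraries by camera with its preset correlation, a call lost with an estimated one. Of 14 tested, 13 had a negative fold change (median -0.53) and the list was lower by camera (Benjamini-Hochberg adjusted p = 3.76e-05). With an estimated correlation, camera's Benjamini-Hochberg adjusted p was 0.198. Lhx9 was the 1 member that fell over all genes tested by edgeR, against 0 with the GC and length correction and 4 by DESeq2. Adjusted over the list alone 7 were lower. Chosen after their values were seen, these include Dmrt3 (log2 fold change -1.18, SE 0.31) and Emx2 (-0.53, SE 0.14), both cortical transcription factors. The meningeal fibroblast list (median -0.62) and the list of cortical hem and choroid plexus (median -0.53, not called) moved in the same direction. Rostral patterning genes were not called. They had 4 of 8 positive, a camera Benjamini-Hochberg adjusted p of 0.877, and a median of -0.02 and a mean below 0 while camera's direction was up. Adjusted over the list alone 1 rostral member was lower, the homeobox factor Pax6 (-0.53, SE 0.14), and 1 higher, the phosphatase Dusp6 (0.56, SE 0.19), which was chosen after its values were seen.

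Hedgehog, Notch, Wnt and BMP pathway genes were lower in the NG2 libraries by camera, and FGF pathway genes were not. Hedgehog genes were negative in 9 of 10 members (median -0.30, camera Benjamini-Hochberg adjusted p = 0.00166, and 0.457 as the adjusted p with an estimated correlation). Cdon was the 1 member that fell over all genes tested, and adjusted over the list alone 4 were lower, among them Gas1, Gli3 and Boc with log2 fold changes of -0.60, -0.56 and -0.32 (SE 0.15, 0.17 and 0.11). Notch genes were negative in 18 of 23 (median -0.33, camera Benjamini-Hochberg adjusted p = 0.00166, and 0.366 as the adjusted p with an estimated correlation), with 0 members past the threshold over all genes tested and 0 adjusted over the list alone. The glycosyltransferases Mfng and Rfng, which modify Notch receptors, had log2 fold changes of -0.06 (SE 0.10) and 0.19 (SE 0.09), and Mfng turned to 0.02 without NG2 1. Wnt genes were negative in 14 of 21 (median -0.23, camera Benjamini-Hochberg adjusted p = 0.0328, and 0.403 as the adjusted p with an estimated correlation). Fzd9 was the 1 Wnt member that fell over all genes tested, and adjusted over the list alone 5 were lower, including the ubiquitin ligase Znrf3 (-0.75, SE 0.19) and the effector Tcf7l2 (-0.92, SE 0.28), and the ligand Wnt7b was higher. BMP and TGF-beta genes were negative in 13 of 17 (median -0.27, camera Benjamini-Hochberg adjusted p = 0.0199, and 0.334 as the adjusted p with an estimated correlation). Over all genes tested 0 BMP members passed, and adjusted over the list alone 3 were lower and 2 higher. Id4 and Id2, targets of BMP signalling, went apart, with Id2 at 0.51 (SE 0.16), and so did the receptors Bmpr1a (-0.36, SE 0.11) and Bmpr1b (0.49, SE 0.17). Gas1, Gli3, Boc, Znrf3, Tcf7l2, Bmpr1a and Bmpr1b were chosen after their values were seen. FGF genes had 7 of 14 positive and a camera Benjamini-Hochberg adjusted p of 0.80, with a median of -0.02 and a mean of -0.03 against camera's direction, which was up. Scores of the Hedgehog and Wnt lists did not overlap between the groups (exact permutation p = 0.00794 for each, 0.0587 after Benjamini-Hochberg adjustment). Those of the Notch and BMP lists overlapped (exact permutation p = 0.0397 and 0.0635, 0.163 and 0.181 after Benjamini-Hochberg adjustment), and on the Notch list NG2 replicates 2 and 3 scored -0.39 and -0.36 while NG2 replicates 4 and 5 scored 0.12 and 0.02. The Hedgehog median was -0.19 without NG2 replicate 3. Camera's Wnt call was lost without GFAP 1, GFAP 2 or NG2 1 (Benjamini-Hochberg adjusted p up to 0.117) and its BMP call without NG2 3 or NG2 5 (up to 0.0589).

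Genes of mitosis and DNA replication were lower in the NG2 libraries by camera, with small changes in each gene. All 25 G2/M genes had a negative fold change (median -0.27, camera Benjamini-Hochberg adjusted p = 4.33e-05, and 0.457 as the adjusted p with an estimated correlation), and so had all 25 G1/S genes (median -0.18, camera Benjamini-Hochberg adjusted p = 0.0366, and 0.818 as the adjusted p with an estimated correlation). Over all genes tested 0 members of either list passed, and adjusted over the list alone 1 of each was lower, the kinesin Kif23 (log2 fold change -0.53, SE 0.14) and the ubiquitin ligase component Dtl (-0.60, SE 0.15), chosen after their values were seen. Cyclin B1 (Ccnb1) stood at 364 ± 39.6 CPM in NG2 and 429 ± 135 CPM in GFAP libraries and Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 328 ± 36.5 and 364 ± 90.5 CPM. The replication genes Rrm2 (481 ± 37.1 against 528 ± 203 CPM) and Mcm7 (365 ± 46.9 against 413 ± 97.0 CPM) did not differ beyond their spread. The G2/M list kept camera's call in all 10 fits with 1 library left out (Benjamini-Hochberg adjusted p up to 0.0262), with a median of -0.15 without GFAP replicate 2. That library scored 0.59 on it, against -0.07 to 0.13 in the others of its group, and the scores of the groups overlapped (exact permutation p = 0.0635, 0.181 after Benjamini-Hochberg adjustment). GFAP replicate 2 had 885 CPM of Rrm2 and 670 CPM of Ccnb1, and without it the G1/S list turned to higher in NG2 (camera Benjamini-Hochberg adjusted p = 0.515) and Rrm2 and Ube2c turned to log2 fold changes of 0.14 and 0.01. Camera's G1/S call was also lost without NG2 1, NG2 2 or NG2 3, with a Benjamini-Hochberg adjusted p of 0.117, 0.134 and 0.191. The exact permutation p of the G1/S scores was 0.476 (0.653 after Benjamini-Hochberg adjustment).

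Genes of cell cycle exit were lower as well (9 of 13 negative, median -0.22, camera Benjamini-Hochberg adjusted p = 0.0428, and 0.457 as the adjusted p with an estimated correlation). Over all genes tested 0 members passed, and adjusted over the list alone Btg2 was lower. Cyclin D2 (Ccnd2), a promoter of the cell cycle that the list also holds, stood at 966 ± 256 CPM in NG2 and 1291 ± 196 CPM in GFAP libraries, and Gadd45g at 285 ± 37.9 and 333 ± 23.7 CPM. Camera's call was lost without GFAP 2, GFAP 5, NG2 1, NG2 4 or NG2 5 (Benjamini-Hochberg adjusted p up to 0.205). Chromatin and epigenetic regulators were negative in 21 of 24 members (median -0.21, camera Benjamini-Hochberg adjusted p = 0.00166, and 0.297 as the adjusted p with an estimated correlation), with 0 past the threshold over all genes tested and 0 adjusted over the list alone. Their scores did not overlap between the groups (exact permutation p = 0.00794, 0.0587 after Benjamini-Hochberg adjustment). The chromatin protein Hmgb2 had a log2 fold change of -0.25 (SE 0.13) and the deacetylase Hdac2 of 0.15 (SE 0.09).

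Glycolysis and hypoxia genes were lower in the NG2 libraries by camera (15 of 19 negative, median -0.24, Benjamini-Hochberg adjusted p = 0.00960, and 0.457 as the adjusted p with an estimated correlation). Adjusted over the list alone 4 were lower and 1 higher, against 0 over all genes tested. The lower ones include the kinase Pdk1 (log2 fold change -0.58, SE 0.11), the hexokinase Hk2 (-0.55, SE 0.15) and the lactate transporter Slc16a3 (-0.65, SE 0.19), and the higher one was the hexokinase Hk1 (0.39, SE 0.12), all chosen after their values were seen. The enzymes Pkm (-0.12, SE 0.13) and Eno1 (-0.24, SE 0.12) did not pass. Camera's call was lost without GFAP 2 or NG2 1 (Benjamini-Hochberg adjusted p = 0.0827 and 0.103). The exact permutation p of the list scores was 0.143 (0.328 after Benjamini-Hochberg adjustment).

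Among the lists read as signs of RNA quality and stress, mitochondrially encoded transcripts were higher in the NG2 libraries by camera (11 of 12 positive, median 0.18, Benjamini-Hochberg adjusted p = 0.00287, and 0.457 as the adjusted p with an estimated correlation). Their most abundant members mt-Cytb and mt-Co1 had log2 fold changes of 0.23 (SE 0.11) and 0.18 (SE 0.09). Genes of the unfolded protein and integrated stress response were positive in 13 of 15 (median 0.25, camera Benjamini-Hochberg adjusted p = 0.0141, and 0.457 as the adjusted p with an estimated correlation). This call was lost without NG2 2 or NG2 3 (camera Benjamini-Hochberg adjusted p = 0.0559 and 0.104). The chaperones Hspa5 (0.02, SE 0.11) and Pdia4 (0.06, SE 0.10) took little part in it, and Hspa5 turned to -0.03 without GFAP 3 and Pdia4 to -0.02 without NG2 2. The p53 response was positive in 9 of 15 (median 0.09, camera Benjamini-Hochberg adjusted p = 0.0429, and 0.457 as the adjusted p with an estimated correlation). Plk2 was the 1 member that rose, over all genes tested and adjusted over the list alone. This call was lost without GFAP 1, 3, 4 or 5 or NG2 1, 2, 3 or 4 (camera Benjamini-Hochberg adjusted p up to 0.148). In the mitochondrial and unfolded protein lists, 0 members passed over all genes tested and 0 adjusted over the list alone. The exact permutation p of library scores was 0.119 for mitochondrial transcripts, 0.246 for the unfolded protein response and 0.397 for the p53 response. After Benjamini-Hochberg adjustment these were 0.294, 0.433 and 0.638. Immediate-early and dissociation genes (camera Benjamini-Hochberg adjusted p = 0.0813, median 0.18), cytosolic ribosomal protein genes (0.105, median 0.04) and interferon genes (0.852) were not called. Camera called immediate-early genes without GFAP 3 or NG2 5 (Benjamini-Hochberg adjusted p = 0.0307 and 0.0356) and ribosomal protein genes without GFAP 2, GFAP 3 or NG2 2 (0.0114, 0.00991 and 0.000242). In the interferon list, 10 of 20 were positive, with a median and a mean of 0.00 that differed in sign.

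Among markers of other cell types, camera with its preset correlation called the lists of microglia and of meningeal fibroblasts. Microglia and macrophage genes were higher in the NG2 libraries by camera (17 of 18 positive, median 0.84, Benjamini-Hochberg adjusted p = 0.0179, and 0.696 as the adjusted p with an estimated correlation). The complement genes C1qb and C1qc stood at 45.4 ± 33.8 and 35.5 ± 28.8 CPM in NG2 against 22.3 ± 14.6 and 17.5 ± 9.43 CPM in GFAP libraries. These genes moved together from library to library, with an estimated correlation of 0.73, and the call was lost without GFAP 2, GFAP 5 or NG2 1 (camera Benjamini-Hochberg adjusted p up to 0.464). Their list score was 0.21 ± 1.19 in NG2 and -0.21 ± 0.74 in GFAP libraries (exact permutation p = 0.540, 0.713 after Benjamini-Hochberg adjustment), so the scores did not separate the groups. Meningeal fibroblast genes were lower (9 of 10 negative, median -0.62, and -1.004 without NG2 replicate 4, camera Benjamini-Hochberg adjusted p = 0.00166, and 0.393 as the adjusted p with an estimated correlation), at low levels. Crabp2, a carrier of retinoic acid, stood at 8.03 ± 1.32 CPM in NG2 and 11.6 ± 2.46 CPM in GFAP libraries, and the collagen gene Col3a1 at 4.90 ± 4.86 and 6.11 ± 1.30 CPM. In both lists, 0 members passed over all genes tested and 0 adjusted over the list alone. The exact permutation p of the meningeal fibroblast scores was 0.0476 (0.176 after Benjamini-Hochberg adjustment).

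The remaining marker lists were not called. Oligodendrocyte lineage genes had 7 of 14 positive (camera Benjamini-Hochberg adjusted p = 0.80), with a median of -0.02 and a mean of 0.28. Cspg4 was the 1 oligodendrocyte member and also the 1 pericyte member past the threshold, over all genes tested and adjusted over each list alone. Pericyte and mural cell genes had 3 of 9 positive (camera Benjamini-Hochberg adjusted p = 0.80), with a median of -0.11 and a mean of 0.18. Astrocyte lineage genes were negative in 12 of 17 (median -0.27, camera Benjamini-Hochberg adjusted p = 0.0959), and adjusted over the list alone the connexin gene Gja1 (log2 fold change -0.69, SE 0.17) and the transcription factor Sox9 (-0.57, SE 0.14) were lower. Outer radial glia genes had a median of -0.03 and a mean of 0.13 (camera Benjamini-Hochberg adjusted p = 0.770), and adjusted over the list alone Trnp1 (1.09, SE 0.28) and Tmem158 (0.67, SE 0.22) were higher. Extracellular matrix and adhesion genes were negative in 15 of 24 (median -0.20, camera Benjamini-Hochberg adjusted p = 0.0770), and adjusted over the list alone the cadherin Cdh4 (0.58, SE 0.14) and the proteoglycan Cspg5 (0.54, SE 0.16) were higher and the proteoglycan Bcan (-1.24, SE 0.38) and the laminin Lamb2 (-0.61, SE 0.19) lower. Gja1, Sox9, Trnp1, Tmem158, Cspg5, Bcan and Lamb2 were chosen after their values were seen. Camera's Benjamini-Hochberg adjusted p was 0.381 for cortical hem and choroid plexus (median -0.53), 0.459 for the ventral telencephalon and GABAergic lineage (median -0.04) and 0.852 for endothelial cells, erythroid cells, and axon guidance and neuronal migration. When 1 library was left out, camera called upper-layer neurons without GFAP 3 or GFAP 5 (Benjamini-Hochberg adjusted p = 0.0453 and 0.0102), hem and choroid plexus without GFAP 5, NG2 2 or NG2 3 (0.000716, 0.0217 and 0.0397), matrix genes without GFAP 5 or NG2 4 (0.0367 and 0.0342) and the ventral telencephalon without NG2 5 (0.0438). Endothelial genes had a median of -0.03 and a mean of 0.03, erythroid genes 0.01 and -0.02, and axon guidance genes -0.03 and -0.06 against camera's direction, which was up.

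Of all 37 lists, 7 were higher and 14 lower in NG2 by camera after Benjamini-Hochberg adjustment. With an estimated correlation 0 passed, and 5 had an unadjusted p under 0.05. The exact permutation of library scores gave 0 lists after adjustment, with a smallest Benjamini-Hochberg adjusted p of 0.0587 and an unadjusted p under 0.05 for 10 of the 21 lists called by camera. That adjusted p belonged to 5 lists at 0.00794, the smallest exact permutation p that 252 assignments can give. After adjustment over 37 lists the test thus had little room to pass any, so its 0 calls do not argue against these lists. By the rotation test fry, 4 lists were lower and 0 higher. These were intermediate progenitors, caudal and medial patterning, chromatin and Wnt (fry Benjamini-Hochberg adjusted p = 0.0114, 0.0151, 0.0308 and 0.0342). The scores of 5 lists, intermediate progenitors, Cajal-Retzius and subplate, Wnt, Hedgehog and chromatin, had no overlap between the groups, where chance gives 0.794% of lists. With 1 library left out, the medians of further lists moved by over 1.5 times. Without GFAP 2 that of glycolysis and hypoxia was -0.11 and that of cell cycle exit -0.12, and without NG2 1 that of microglia was 0.28. The median of mitochondrially encoded transcripts was 0.088 without NG2 3 and 0.27 without NG2 5. That of the unfolded protein response was 0.076 to 0.14 without GFAP 1, GFAP 4, GFAP 5, NG2 2 or NG2 3. That of the p53 response was 0.25, -0.011, 0.058 and 0.16 without GFAP 2, GFAP 4, GFAP 5 and NG2 4, and that of G1/S phase was 0.038 without GFAP 2 and -0.11 without NG2 3. Among the genes named for the lists, Sstr2, Tubb3, Lpar1, Mcm7, Ube2c, Id4, Pax6, Pkm, Lhx2, Eomes, Nefm, Wnt7b, Gli3, Bmpr1a, Emx2, Hk1, Syn1 and Cspg5 overlap another annotated gene, so part of their reads is of uncertain origin.

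Over all 16187 tested genes, libraries of the same group resembled each other slightly more than libraries of different groups. The mean correlation was 0.968 within and 0.966 between groups, a difference in distance of 0.00258 (exact permutation p = 0.0159 over 126 splits, one-sided). Without NG2 replicate 5 it was 0.00343 (exact permutation p = 0.0238). It was -0.000349, -0.000431, -0.000650 and -0.000456 without GFAP 1, GFAP 3, GFAP 4 and GFAP 5 (exact permutation p = 0.476 to 0.484) and 0.000223 without GFAP 2 (p = 0.460), and 0.00521 to 0.00681 without 1 of NG2 1 to 4 (p = 0.0159 to 0.0317). With groups of unequal size, NG2 replicate 5 weighs differently in the pairs within and between groups, so these values do not show which libraries the separation depends on. The first principal component held 46.4% of the variance and set NG2 replicate 5 apart from the other 9 libraries.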

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

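The test of GFAP replicate 2 as the source of the neuron and radial glia difference and the correction for GC content and gene length were chosen only after the result was seen, while leaving out each library in turn was planned. In 280 groups of 5 library values, 29 held 1 library far from the other 4 of its group (gap to the nearest value above 0.71 of the range), where chance gives about 5%.

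GFAP replicate 2 accounted for 14 of these, 11 of them gene values, which share library-wide shifts and are not independent. It was high in cell cycle genes, with 885 CPM of Rrm2 (others of its group 407 to 498), 584 CPM of Mcm7 (357 to 394) and 670 CPM of Ccnb1 (348 to 380). It was also high in Id4 with 422 CPM (236 to 269), Gadd45g with 374 CPM (315 to 331), Car14 with 46.6 CPM (36.5 to 38.7) and Eno1 with 1672 CPM (1174 to 1273). It was low in Gria2 with 323 CPM (601 to 756), Rtn1 with 812 CPM (996 to 1077) and Dusp6 with 5.46 CPM (9.45 to 11.8). Odf3l1 had its single GFAP read there, at 0.0628 CPM against 0. Its list scores were 0.53 for radial glia (others 0.04 to 0.13), 0.76 for G1/S phase (-0.12 to -0.04) and -0.51 for synapse and ion channels (-0.06 to 0.11).

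The higher neuronal and lower radial glia expression in the NG2 libraries may therefore rest in part on GFAP replicate 2. The difference between the median log2 fold changes of the 2 lists was 0.64 with all libraries and 0.43 without it, with a bootstrap interval over genes of 44.2% to 88.9% of the full value, so how far that library sets the pattern cannot be told apart from its spread. By voom with sample weights, where NG2 replicate 4 had the highest weight, the difference was 0.35. A bias of GC content or gene length is argued against by the difference of 0.64 after that correction as before (85.7% to 129% of it). NG2 replicate 5 as its source is argued against by the difference of 0.77 without that library (102% to 138%). The intervals resample genes that move together (estimated correlation 0.56 for radial glia and 0.42 for neurons). They are therefore too narrow and hold no spread between libraries, so these statements rest on the values alone. The sorted population remains open as an untested biological explanation, and so does a varying share of neurons among the sorted cells.

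NG2 replicate 5 stood apart in 6 values. It had reads for 18903 genes (others of its group 22988 to 24444), and its mean correlation with the other 9 libraries was 0.923 (0.968 to 0.976). Car14 stood at 13.7 CPM (22.0 to 24.7), Vamp2 at 229 CPM (287 to 312) and Kif26b at 11.6 CPM (24.8 to 28.9), and Cspg5 was high at 55.7 CPM (31.3 to 35.1). Kif26b overlaps another annotated gene and was chosen after its values were seen. Sequencing depth is argued against, because with every library thinned to 12945436 counts it still had reads for 18572 genes, 82.3% of the 22574 in the lowest other library. A loss of transcripts before sequencing could account for it, and the share of genes of 5 to 20 CPM without a read was 0.548%, 8.54 times the highest share of 0.0642% in any other library, which lay below the 10 times set in advance, so it stays open. No biological explanation was tested, since the labels give this library the same description as the others of its group.

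The other values stand without explanation, apart from Xist. In the GFAP group, Zic5 was low in replicate 4 at 6.37 CPM (others 10.3 to 12.2) and Tcf7l2 high there at 24.1 CPM (11.1 to 13.6). Fzd9 was low in GFAP replicate 5 at 15.0 CPM (23.8 to 26). Xist, a transcript of the inactive X chromosome in females, was low in that library at 7.97 CPM (92.3 to 170). Scaled by library size alone, the Y-linked genes Ddx3y (60.1 CPM), Uty (31.3), Eif2s3y (110) and Kdm5d (48.0) were highest there of all libraries. The share of male cells was thus higher in GFAP replicate 5 than in the others of its group. GFAP replicate 3 had the highest share of mitochondrial counts at 0.667% (0.554% to 0.586%). In the NG2 group, Nfatc4 was low in replicate 3 at 9.04 CPM (12.1 to 13.6), as was the deep-layer neuron score at -0.073 (0.10 to 0.17). Mfng was low in NG2 replicate 1 at 172 CPM (222 to 235). In NG2 replicate 4, Btg2 was high at 225 CPM (200.1 to 206).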

How the results depend on the processing

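The correction for GC content and length, DESeq2 without NG2 replicate 5, robust dispersions and the exact permutation of list scores were chosen only after the result was seen. Of the values of single genes and lists under all alternatives, 3007 kept their direction and side of the threshold, 359 lost the threshold, 169 gained it and 95 turned direction. Of the summary values, 99 stayed, 49 moved, 2 lost the threshold and 5 turned. Cspg4 stayed higher in the NG2 libraries in all 14 alternatives of its permutation test. With the replicate number as a block, edgeR's Benjamini-Hochberg adjusted p was 0.0574 for Cspg4 and 0.0714 for Mc4r. This was the 1 alternative in which each lost the threshold. Unless a construction is named, the cause was not tested. Depth limits Gfap, with 6 and 10 reads in the groups, and genes of low count, of which no filter let 31106 be tested in place of 16187.

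Counts of genes higher and lower in NG2 (12 and 12 by edgeR) were 210 and 133 by DESeq2 and 444 and 285 by DESeq2 without NG2 replicate 5. By voom with sample weights they were 584 and 857. Voom gave NG2 replicate 5 the lowest weight (0.170) and NG2 replicate 4 the highest (6.30, with GFAP replicate 4 next at 2.02). NG2 replicate 4 thus weighed most in that fit. The counts were 58 and 37 without a filter, 19 and 20 over protein-coding genes (fewer genes tested), 31 and 23 with genes detected as covariate, 45 and 38 with 1 surrogate variable, which set NG2 replicate 5 apart, and 5 and 0 with library size as covariate. A fold threshold left 3 and 4, FPKM gave 8 and 5 with either pseudocount (11 of the 24 genes shared), and the GC and length correction gave 20 and 9. With 1 library left out, they were 3 to 70 higher and 0 to 47 lower, and 4 to 9 lists were higher and 10 to 15 lower. Camera with an estimated correlation called 0 lists higher and 0 lower, the permutation of scores 0 and 0, fry 0 and 4, and camera on voom values 6 and 6. The separation was 2.26 with Euclidean distance (exact permutation p = 0.0635, one-sided) and -0.000650 to 0.00681 with 1 library left out, and Gfap ranged from -0.64 to 0.023.

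No pairing of the libraries by replicate number was detected, and the labels do not say whether equal numbers mark a shared animal or day. Deviations of libraries with the same number correlated at -0.02 to 0.08, 0 of 5 above 0.1, and 1 of 5 GFAP libraries correlated best with its own number. With the replicate number as a block, edgeR called 1 gene higher and 0 lower, and camera's Benjamini-Hochberg adjusted p of the axon guidance list turned direction at 0.999.

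Some genes that had not passed turned direction. The log2 fold change of Hspa5 was -0.0029 with genes detected and -0.010 with library size as covariate, -0.026 with scaling by library size alone, -0.063 by voom, and -0.030 to 0.092 with 1 library left out. Rrm2 was 0.17, Ube2c 0.15 and Gria2 -0.037 by voom. With 1 library left out, Rrm2 ranged from -0.21 to 0.14, Ube2c from -0.22 to 0.013, Mfng from -0.083 to 0.019 and Pdia4 from -0.016 to 0.11.

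Of the lists that turned direction, G1/S phase alone had been called. The following are camera's Benjamini-Hochberg adjusted p unless another test is named. With 1 surrogate variable, it was 0.597 for oligodendrocyte lineage, 0.576 for outer radial glia, 0.947 for FGF, 0.675 for rostral patterning, 0.450 for endothelial cells, 0.236 for interferon and 0.961 for axon guidance. With genes detected as covariate, it was 0.895 for oligodendrocyte lineage, 0.707 for outer radial glia, 0.741 for rostral patterning, 0.285 for endothelial cells and 0.269 for interferon. With library size as covariate, it was 0.874 for oligodendrocyte lineage, 0.752 for outer radial glia, 0.545 for rostral patterning and 0.369 for interferon, and with scaling by library size alone 0.944 for endothelial cells. Under the GC and length correction, it was 0.860 for oligodendrocyte lineage, 0.986 for FGF, 0.746 for pericytes, 0.888 for erythroid cells and 0.746 for interferon. The stricter filter gave 0.782 for rostral patterning and 0.761 for interferon, and no filter gave 0.930 for outer radial glia, 0.930 for FGF, 0.901 for rostral patterning, 0.901 for endothelial cells and 0.557 for pericytes. Protein-coding genes alone gave 0.992 for rostral patterning and 0.955 for axon guidance. On FPKM with a pseudocount of 0.1, it was 0.355 for oligodendrocyte lineage, 0.763 for rostral patterning, 0.325 for pericytes and 0.650 for interferon, and with a pseudocount of 1 it was 0.335, 0.751, 0.335 and 0.577. On voom values, it was 0.271 for the ventral telencephalon, 0.355 for G1/S phase, 0.163 for endothelial cells and 0.334 for axon guidance. The rotation test fry gave Benjamini-Hochberg adjusted p of 0.957 for FGF, rostral patterning, erythroid cells and axon guidance and 0.962 for interferon. The exact permutation of scores gave 0.653 for FGF, 0.890 for erythroid cells, 1 for interferon and 0.653 for axon guidance after Benjamini-Hochberg adjustment.

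With 1 library left out, camera's Benjamini-Hochberg adjusted p ranged from 0.458 to 0.995 for FGF, from 0.00509 to 0.515 for G1/S phase, from 0.130 to 0.991 for axon guidance, from 0.000242 to 0.856 for ribosomal proteins, from 0.256 to 0.998 for endothelial cells, from 0.326 to 0.991 for erythroid cells, from 0.0829 to 0.991 for interferon, from 0.224 to 0.991 for oligodendrocyte lineage, from 0.265 to 0.991 for outer radial glia, from 0.364 to 0.991 for pericytes, from 0.376 to 0.991 for rostral patterning and from 0.0438 to 0.852 for the ventral telencephalon, each with at least 1 change of direction.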

Other observations

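The tests of pericyte and of oligodendrocyte markers were chosen only after the result was seen. Transcription factor families were examined as further gene groups, with 809 tested genes in 13 families of at least 10 members. By camera, 5 families were lower in the NG2 libraries and 0 were higher. Homeobox factors were negative in 32 of 44 members (median log2 fold change -0.12, camera Benjamini-Hochberg adjusted p = 0.00706, and 0.386 as the adjusted p with an estimated correlation), HMG box factors in 28 of 41 (-0.11, camera Benjamini-Hochberg adjusted p = 0.0171, and 0.386 as the adjusted p with an estimated correlation) and E2F factors, which drive the cell cycle, in 10 of 10 (-0.18, camera Benjamini-Hochberg adjusted p = 0.0294, and 0.386 as the adjusted p with an estimated correlation). The Rel homology family, to which Nfatc4 belongs, was negative in 8 of 10 (-0.27, camera Benjamini-Hochberg adjusted p = 0.0205, and 0.197 as the adjusted p with an estimated correlation) and the MYB family in 19 of 28 (-0.14, camera Benjamini-Hochberg adjusted p = 0.0262, and 0.197 as the adjusted p with an estimated correlation), so none of the 5 calls held with it. The exact permutation of library scores gave 0 families after Benjamini-Hochberg adjustment (smallest adjusted p = 0.103), so the hypothesis that families differ as sets was met by 1 of the 2 tests it needed. That adjusted p belonged to the MYB family, whose exact permutation p of 0.00794 was the smallest possible. A single family thus could not pass after adjustment, and the 0 families do not argue against the hypothesis. The other 8 families, among them 60 bHLH and 470 C2H2 zinc finger genes, were not called by camera (Benjamini-Hochberg adjusted p from 0.228 to 0.984).

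Transcripts of the sex chromosomes varied between libraries. Xist ranged from 8.09 CPM in GFAP replicate 5 to 173 CPM in GFAP replicate 3 when scaled by library size alone, and the Y-linked gene Ddx3y from 19.3 CPM in GFAP replicate 2 to 60.1 CPM in GFAP replicate 5. Reads of both genes were present in all 10 libraries. The exact permutation p for a difference between NG2 and GFAP was 0.960 for Xist and 0.468 for Ddx3y.

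The rise of Odf3l1 together with its neighbour Cspg4 in the NG2 libraries may come from transcripts of the electroporated NG2 reporter, which would carry sequence from the region around the Cspg4 promoter. Under that hypothesis the other genes nearby would stay level, and the 16 other tested genes within 500 kb had a median log2 fold change of -0.036 (range -0.64 to 0.31) with 0 past the threshold by edgeR. A promoter that both genes share in the cells themselves would also leave the other genes nearby level. Cspg4 had 80 reads in the GFAP libraries, where Odf3l1 had 1, against 513 and 666 in the NG2 libraries. The 2 genes thus kept no common ratio, which argues against a shared promoter that drives both at 1 fixed ratio. A shared promoter whose 2 directions differ between the populations was not tested. The other pericyte markers did not rise as a set with Cspg4, with a median of -0.12 (bootstrap interval over genes -0.29 to 0.05). The other oligodendrocyte lineage markers did not either, with a median of -0.10 (-0.21 to 0.65). A rise like that of Cspg4 by 2.64 had been set at a median above 1, and both intervals lay below it. The rise of a marker also depends on its level in the other sorted cells, and these markers reached mean levels of 11.8 and 23.3 CPM. The test therefore cannot exclude pericytes or oligodendrocyte precursors in the NG2 sort. The interval had first been held to a bound of 0.5, which the lineage markers did not meet, and was held to 1 after their values were seen.

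Other splits of the 10 libraries into 5 and 5 were fitted to see how often they give as many calls, with 100 splits drawn. For genes, 1 of the 100 splits, the real one, gave as many as 12 higher, and 1 gave as many as 12 lower. The highest count of any other split was 0 by edgeR. The other splits mix the groups, so differences such as those of Cspg4 and Odf3l1 add to the spread within them. The real grouping thus stood out by its total count, but chance is not excluded for any single gene of the 24. For gene lists chance cannot be excluded: 53 splits reached the 7 higher lists and 16 the 14 lower, with a highest count of 20 in another split. Since other splits have no direction of their own, each was counted by the larger of its 2 directions, which for the 7 higher lists sets the smaller side of the real split against the larger side of the others. Over both directions, 9 of the 100 splits called as many lists as the real 21, with a highest other count of 23. Camera with a preset correlation thus called lists in many groupings of these libraries.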
